A study of Mus musculus with 5 samples.

How the data were processed

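Total RNA of cDC1s from the visceral adipose tissue of wild-type mice was sequenced in bulk. Per the labels' protocols, the fat was cut up and digested with collagenase and DNase at 37°C with shaking, adipocytes were removed by centrifugation and red blood cells were lysed. The cells were then sorted as CD45-positive, negative for CD3, TCRβ, CD19, Ly6G, NK1.1, CD88 and CD11b, and positive for HLA-DR (as the labels name it), CD11c and XCR1. The labels give their purity as above 95%. The labels name the library preparation only as a standard Illumina protocol.

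The values used were raw read counts per gene, deposited by the authors in one table of 33522 rows named by gene symbol, with a column for each of the 5 libraries. Per the submitters' processing notes, reads were aligned with STAR 2.5.3a and the genome build was mm10. The counting tool, the gene annotation, the strand setting and any filter are not given in the sources used here, so counts of overlapping or antisense genes and of near-identical copies are uncertain. Of the row names, 26 had been turned into dates by a spreadsheet, and 4 of those rows share a name with another. These rows stayed in the fit and are not named. Library totals ran from 4542696 to 14426313 counts, and after TMM scaling 3 counts correspond to between 0.148 CPM (HFD 3) and 0.938 CPM (LFD 1). Such floors cover counting error only, since the reads carry no molecular identifiers.

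Libraries were assigned to HFD or LFD from their titles. HFD against LFD was the one comparison, fitted to all 5 libraries with diet as the only term. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 11591 of 19547 genes with any count. Counts were scaled by TMM, and tested 2-sided with edgeR 4.0.16 by its quasi-likelihood test with robust dispersions (R 4.3.3). P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the root of the F statistic. CPM values are scaled by TMM. TMM factors were 1.35 and 1.41 for HFD 1 and HFD 3 and 0.644, 0.723 and 1.14 for LFD 1, LFD 2 and LFD 3. The common dispersion was 1.01, a coefficient of variation between libraries of 100% (rounded). This is one value for all tested genes together, and it does not hold for each gene. The abundant gene Cd74, for example, had a standard error of 0.143. No 2 libraries agreed within sampling noise.

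A set of 32 gene lists was fixed before the data were examined, together with the main test and the rule for named genes. Of these, 28 had at least 5 tested members and were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 28 lists. No list passed with an estimated correlation, while 5 passed with the preset one. Fry, which called 9, asks only whether a list's genes move one way on balance and does not compare them with other genes. For a gene without LFD counts, the lower bound of the fold change is taken against 3 counts over the whole LFD group (0.211 CPM). This bound covers counting error only. Of tested genes with an LFD mean of at least 20 CPM, 74 had no count in at least 1 LFD library.

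The rule for named genes was to take genes past the threshold. As none passed, it fell back on the 6 genes of smallest p in each direction. It also took 10 genes of the IL-12, STING and cDC1 axis whatever their values, up to 4 members of smallest p per list, and for marker and RNA-quality lists the 2 of highest mean CPM. Ciita, Btg2, C5ar1, C1qa, C1qb, C1qc, Cd68, Apoe, Csf1r, Cd14, Ly6c2, Trem2 and the genes of the added families were named outside the rule, after their values were seen. Coordinates, transcript lengths and GC contents come from GENCODE release M21 on GRCm38, the assembly of mm10, matched by symbol for 11284 of 11591 tested genes (97.4%). Mb21d1 had no match.

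On counts simulated with the estimated dispersions (9566 genes), the edgeR test called 11% of genes changed by a log2 fold of 2 and 27.4% of those changed by 3, and DESeq2 called 34.1% and 48.8%. Of unchanged genes, edgeR called 0.03% and DESeq2 1.65%. Unchanged genes far outnumbered changed ones (9365 against 82 and 84 tested in edgeR), so the DESeq2 calls included many unchanged genes. DESeq2 calls and adjusted p-values in the data are to be read with that limit. On the simulated counts limma's camera gave a p of 1.18e-06 for a list with shifted members and 0.75 for a list without. With an estimated correlation the p for the shifted list was 0.0124. The simulated genes were drawn independently, so this cannot show how the preset correlation fares on lists whose members move together. In the data the estimated correlation reached 0.98, for mitochondrially encoded genes. Alternatives were DESeq2 1.42.0, limma-voom with and without sample quality weights, DESeq2 size factors, upper-quartile factors or library totals alone, other count filters, other thresholds, a replicate block, removal of mitochondrial and ribosomal protein genes, thinning to one total, and leaving out each library. Settings added after seeing the data left out rRNA-like genes, removed each library's trend on transcript length and GC, kept genes of an average log2 CPM of at least 6, or left out LFD 1 and LFD 2.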

Results

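Conventional type 1 dendritic cells (cDC1s), the dendritic cell subset that cross-presents antigen to CD8 T cells and is a main source of IL-12, were sorted from the visceral fat of wild-type mice. The mice had been fed a low-fat diet (LFD) or a high-fat diet (HFD, labelled 60%) for 4 weeks. RNA of the sorted cells was sequenced in bulk. The HFD group held 2 libraries, numbered 1 and 3, and the LFD group held 3, numbered 1, 2 and 3. Total counts were 9968875 and 14426313 in HFD 1 and HFD 3, and 4981704, 8103598 and 4542696 in LFD 1, LFD 2 and LFD 3. The labels do not say that the libraries came from separate mice, so p-values measure only the spread between these samples, which may be technical.

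The LFD libraries stood apart from the HFD libraries in RNA content. HFD 1 and HFD 3 had counts for 15653 and 17590 genes, and the LFD libraries for 10324, 8958 and 8881. After all libraries were thinned to one total of counts outside rRNA-like and mitochondrial genes, the HFD libraries still had 14251 and 15048 genes and the LFD libraries 10302, 8719 and 8719. Mitochondrial rRNA took 10.8% and 8.07% of the counts in HFD 1 and HFD 3, against 41.7%, 36.0% and 16.6% in LFD 1, LFD 2 and LFD 3. Nuclear genes whose reads resemble rRNA took 7.11% and 6.19% against 11.1%, 12.1% and 9.54%. Log-transformed counts-per-million values (CPM) correlated across genes at 0.959 between the HFD libraries and at 0.682 to 0.713 between LFD libraries. Pairs of an HFD and an LFD library correlated at 0.756 to 0.779. By this measure each LFD library was closer to the HFD libraries than to the other LFD libraries. Of the genes tested, 979 had no count in any LFD library and 17 had none in either HFD library.

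**Figure D1:**
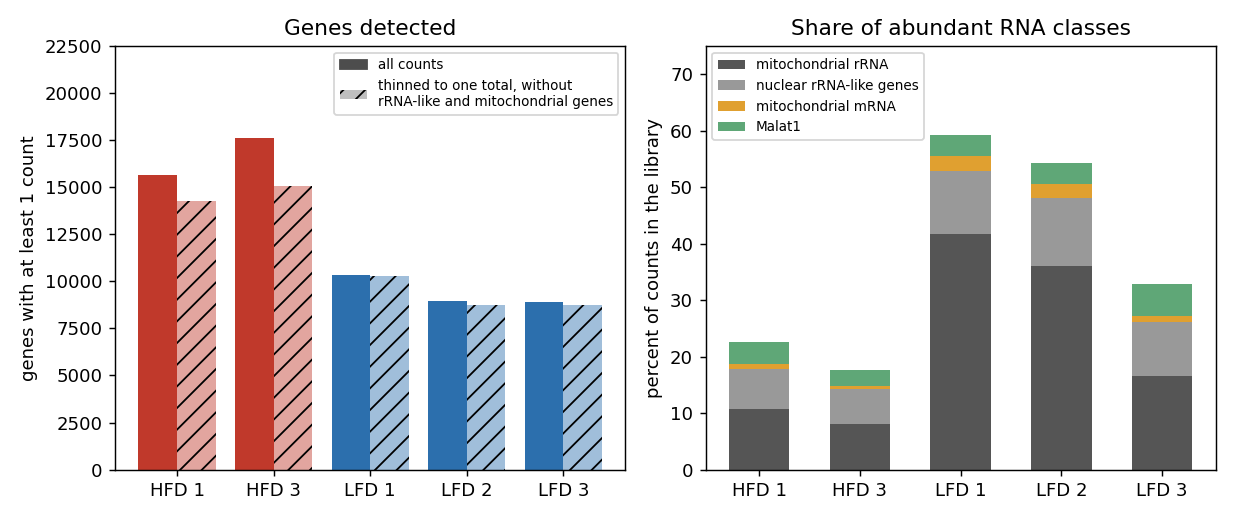
The left panel plots the number of genes with at least 1 count in each library, for all counts (solid bars) and after thinning to one total without rRNA-like and mitochondrial genes (hatched bars), with HFD in red and LFD in blue. The right panel plots the percent of each library's counts in mitochondrial rRNA, nuclear rRNA-like genes, mitochondrial mRNA and Malat1, and mitochondrial rRNA reached 41.7% in LFD 1 against 8.07% in HFD 3.

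The comparison of HFD with LFD asked which transcripts of adipose cDC1s differ after 4 weeks of high-fat feeding, in a study whose title concerns STING and IL-12. The 6 genes with the smallest p among those higher in HFD were Mpeg1, Ddx3x, Mob1a, H2-Aa, Mbnl1 and P2ry10, and none passed the main test. Mpeg1, which encodes the pore-forming protein perforin-2 of phagocytes (chromosome 19, 12460779 to 12465283, GRCm38/mm10), had 1492 ± 198 CPM in HFD and 489 ± 62.6 CPM in LFD (SD, n = 2 and 3), a log2 fold change of 1.61 ± 0.18 (SE). H2-Aa, the alpha chain of the MHC class II molecule I-A (chromosome 17, 34282744 to 34287823), had 2763 ± 461 against 1225 ± 108 CPM, a log2 fold change of 1.17 ± 0.16. The RNA helicase gene Ddx3x (chromosome X, 13280970 to 13294052) had a log2 fold change of 1.45 ± 0.17, and Mob1a, an adaptor of Hippo signalling (chromosome 6, 83326016 to 83343776), one of 1.98 ± 0.27. The splicing regulator Mbnl1 (chromosome 3, 60472830 to 60629750) had 1.12 ± 0.16, and the lysophospholipid receptor family gene P2ry10 (chromosome X, 107088492 to 107104974) had 1.62 ± 0.24.

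The 6 with the smallest p among genes lower in HFD were Hspa1a, Smarca2, Zfhx3, Nav1, Mir6236 and Hspa1b. Hspa1a, an inducible HSP70 chaperone (chromosome 17, 34969190 to 34972156), had 27.9 ± 7.19 CPM in HFD and 367 ± 47.5 CPM in LFD, a log2 fold change of -3.71 ± 0.28 (SE). Its near-identical neighbour Hspa1b (chromosome 17, 34956436 to 34959238) had a log2 fold change of -4.20 ± 0.50. Reads can be split between these copies, and their summed level was 52.3 ± 1.23 CPM in HFD and 816 ± 262 CPM in LFD. Smarca2, the BRM ATPase of SWI/SNF chromatin remodelling (chromosome 19, 26605050 to 26778322), had 182 ± 10.8 against 528 ± 21.8 CPM, a log2 fold change of -1.54 ± 0.17. The transcription factor gene Zfhx3 (chromosome 8, 107942644 to 108961630) had -1.77 ± 0.21 and the microtubule-associated gene Nav1 (chromosome 1, 135434580 to 135607295) had -1.33 ± 0.16. Mir6236 (chromosome 9, 110281287 to 110281409) was counted among the rRNA-like genes, and had -3.10 ± 0.37. Transcript GC content was 51.12% to 58.95% in these 6 genes and 36.95% to 50.98% in the 6 higher ones. Over 3443 of the more abundant genes, log2 fold change and GC content correlated at -0.39 (Spearman), and both sets lie along this trend. Both kept their signs with each library's length and GC trends removed, where 0 of them passed.

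All 12 of these genes separated the HFD from the LFD libraries without overlap, which their choice by smallest p favours. So did 41.2% of the genes tested, where chance gives 20%. That share counts genes without any LFD count, of which 979 were tested, so it does not measure an effect of diet. The adjusted p of the 12 was 0.0735 in edgeR's quasi-likelihood test, the smallest of any gene and shared by 463 genes. The main test called 0 of 11591 genes, with 2024 at an unadjusted p under 0.05, of which 1474 were higher and 550 lower in HFD. Of these, 849 higher and 8 lower genes had an average log2 CPM under 1, where 98.9% of genes had no count in at least 1 LFD library, and over a log2 CPM of 7 the balance turned, to 120 higher and 325 lower. DESeq2 called 897 genes (284 higher and 613 lower), limma-voom 146 (117 and 29) and limma-voom with sample quality weights 1678 (1446 and 232). On the simulated counts DESeq2 called 1.65% of unchanged genes, so its calls here can include many such genes. All 12 passed in DESeq2, from an adjusted p of 1.58e-41 for Hspa1a to 2.07e-06 for P2ry10. Of the 12, 7 passed in limma-voom and 11 in limma-voom with sample quality weights. Leaving out HFD 1 gave 68 edgeR calls (18 higher and 50 lower) and leaving out HFD 3 gave 38 (5 and 33). Without LFD 1 and LFD 2, which had the highest mitochondrial rRNA shares, 7492 genes passed, with the spread then taken from the HFD pair alone. The median log2 fold change of all tested genes was 0.28, and it was 0.15 with DESeq2 size factors, 0.20 with upper-quartile factors and 1.01 with library totals alone, and fold changes are to be read against that shift.

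IL-12 and STING transcripts were examined by name. Il12b, the p40 subunit of IL-12 (chromosome 11, 44400063 to 44414033), had 57.1 ± 26.1 CPM in HFD and 50.3 ± 25.7 CPM in LFD, a log2 fold change of 0.18 ± 0.58 (edgeR adjusted p = 0.977). The difference was smaller than the spread within either group, with 38.6 and 75.6 CPM in the HFD libraries and 24.4, 50.8 and 75.8 CPM in the LFD libraries, and its sign turned without HFD 3 (-0.37), without LFD 1 (-0.15), without LFD 1 and LFD 2 (-0.40) and with length and GC offsets (-0.38). Il12a, the p35 subunit (chromosome 3, 68690644 to 68698547), had 1 count in HFD 3 and 0 in the other libraries. Ifnb1 (chromosome 4, 88522025 to 88522774) had 0 counts in all of them. A count of 0 allows up to 3 counts, or 0.148 CPM in HFD 3 and 0.938 CPM in LFD 1, from counting error only. Tmem173, which encodes STING (chromosome 18, 35733679 to 35740554), had 33.7 ± 0.65 CPM in HFD and 11.9 ± 10.3 CPM in LFD, with 0 counts in LFD 3 and a log2 fold change of 1.505 ± 1.60 (edgeR adjusted p = 0.859), which was 0.872 without LFD 3 and up to 1.988 without another library. Mb21d1, which encodes the DNA sensor cGAS, had 14.2 ± 4.79 against 12.6 ± 11.6 CPM, also with 0 counts in LFD 3, and its log2 fold change of 0.17 ± 1.84 turned to -0.21 without HFD 3 and -0.46 without LFD 3.

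Of the list of IL-12 and other dendritic cell cytokines, 15 genes were tested, 8 higher and 7 lower (camera adjusted p = 0.926). Of these, 1 passed adjusted over the list alone and 0 over all genes. Members with the smallest p were Lif, Il1rn, Il6 and Il15, each with no count in the LFD libraries. Il15 and Lif were at 6.56 ± 1.72 and 1.54 ± 0.78 CPM in HFD. Against a floor of 3 counts over the LFD group, their log2 fold changes were 4.96 and 2.87. That floor covers counting error only. The cGAS-STING pathway list had 23 members tested, 13 higher and 10 lower, at a median log2 fold change of 0.32 (camera adjusted p = 0.754). The 4 that passed adjusted over the list alone, Tmem203, Trim32, Slc19a1 and Rnf5, were all without counts in LFD, and 0 members passed over all genes.

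The cDC1 identity list did not pass as a whole. Of 28 members tested, 20 were higher and 8 lower, at a median of 0.33 (camera adjusted p = 0.393). Adjusted over the list alone 5 passed, 4 of them higher, and 0 passed over all genes. DESeq2 called 4 members higher and 2 lower. Among genes of an average log2 CPM of at least 6 the list passed, with 18 members tested (camera adjusted p = 0.00335). Xcr1, the chemokine receptor on which the cells were sorted (chromosome 9, 123852315 to 123862029), had 79.0 ± 12.6 CPM in HFD and 18.7 ± 3.16 CPM in LFD, a log2 fold change of 2.08 ± 0.43 (edgeR adjusted p = 0.0735, DESeq2 adjusted p = 1.95e-05). The acid amidase gene Naaa had 1.04 ± 0.16, the lysosomal thioesterase gene Ppt1 1.87 ± 0.31 and Cd24a 1.13 ± 0.24, and DESeq2 called all of these higher. In limma-voom with sample quality weights, Naaa (adjusted p = 0.0177) and Ppt1 (0.0382) passed, while Xcr1 (0.182) and Cd24a (0.127) did not. The transcription factor genes that specify cDC1s did not separate. Irf8 (chromosome 8, 120736358 to 120756694) had 904 ± 47.8 against 738 ± 204 CPM and Batf3 (chromosome 1, 191097847 to 191108945) had 60.2 ± 2.3 against 120 ± 59.4 CPM. Clec9a, a receptor for dead cells (chromosome 6, 129408862 to 129424763), had 366 ± 55.9 against 340 ± 124 CPM, and its log2 fold change of 0.11 turned to -0.021 with DESeq2 size factors, -0.449 with length and GC offsets, -0.127 without LFD 1 and -0.034 without HFD 1. Without LFD 1 and LFD 2 the signs of Clec9a (-0.356), Irf8 (-0.048) and Batf3 (0.22) turned.

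**Figure D2:**
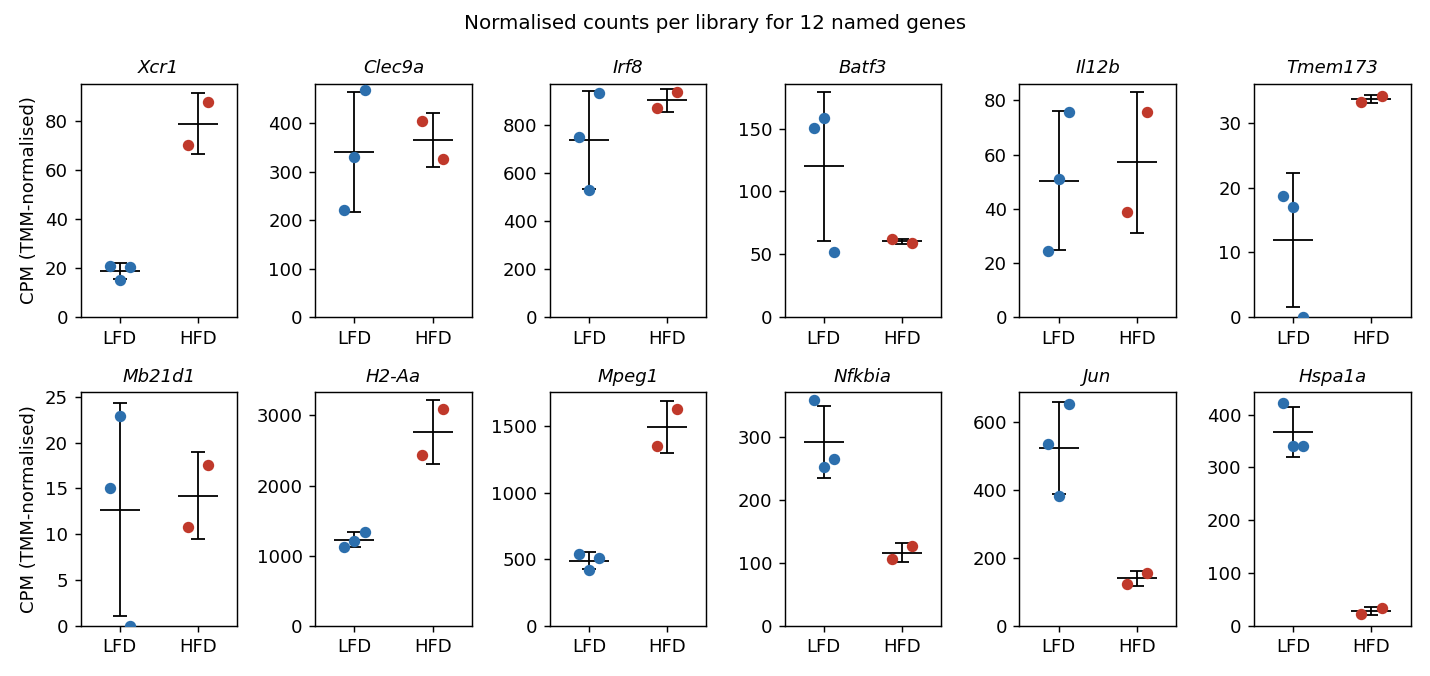
Each panel plots one gene's normalised counts (CPM) on a linear axis from 0, with LFD libraries in blue, HFD libraries in red, and the mean and SD of each group in black (n = 3 and 2). The libraries of the 2 diets did not overlap for Xcr1 (79.0 ± 12.6 against 18.7 ± 3.16 CPM), and overlapped for Il12b (57.1 ± 26.1 against 50.3 ± 25.7 CPM).

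MHC class II presentation genes rose in HFD as a list (camera adjusted p = 0.014, and adjusted p = 0.741 with an estimated correlation). Of 17 members tested, 14 were higher and 3 lower, at a median log2 fold change of 0.86, or 0.58 above the median of all genes. Adjusted over the list alone, 5 passed, of which 4 were higher, and over all genes 0 passed. Cd74, the invariant chain (chromosome 18, 60803848 to 60812652), had 8570 ± 1208 CPM in HFD and 4361 ± 339 CPM in LFD, a log2 fold change of 0.97 ± 0.14. The invariant-chain protease gene Ctss (chromosome 3, 95526786 to 95556403) had 1.28 ± 0.21 and H2-Ab1 (chromosome 17, 34257689 to 34269419) had 0.70 ± 0.14. Ciita, the transactivator of these genes, lay the other way, at 122 ± 16.5 against 217 ± 38.4 CPM and a log2 fold change of -0.84 ± 0.24. The call was lost without HFD 3 (camera adjusted p = 0.0522), without LFD 1 (0.142), without LFD 3 (0.0629), without both LFD 1 and LFD 2 (0.0802) and with length and GC offsets (0.0668). With these offsets the list's median was 0.65, or 0.54 above that of all genes against 0.58 before. The interquartile range of its members went from 0.61 to 0.87. The shift was thus similar and the spread wider, and whether the spread ended the call was not tested. Markers of macrophages, which also present antigen on class II molecules, rose in the same comparison (camera adjusted p = 0.000306, and 0.741 with an estimated correlation), and the LFD libraries had higher mitochondrial rRNA shares and fewer detected genes.

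MHC class I presentation genes did not pass as a list (22 tested, 14 higher and 8 lower, camera adjusted p = 0.762). The list's median was 0.27, against the camera direction, which was down. Adjusted over the list alone 4 passed, 2 of them higher, and 0 passed over all genes. B2m, the light chain of class I molecules, had a log2 fold change of 1.24 ± 0.21 and the peptide-loading gene Pdia3 1.30 ± 0.24. The class Ib genes H2-Q4 and H2-Q6 had -1.31 ± 0.33 and -1.43 ± 0.39, and are uncertain, since they belong to a family of near-identical genes whose reads can be split.

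NF-kB targets fell in HFD as a list (camera adjusted p = 0.000895, and adjusted p = 0.567 with an estimated correlation). Of 32 members tested, 13 were higher and 19 lower, at a median of -0.23, which is 0.51 below the median of all genes, or 0.62 below it with library totals alone, where the list's own median was 0.39. The list's median lay at percentile 8.39 of 10000 random lists matched on mean expression, transcript length and GC content, inside the range of -0.32 to 0.36 that held 95% of them. Adjusted over the list alone 8 passed, 2 of them higher, and 0 passed over all genes. The inflammasome gene Nlrp3 (chromosome 11, 59541568 to 59566956) had 66.9 ± 1.81 CPM in HFD and 203 ± 21.9 CPM in LFD, a log2 fold change of -1.60 ± 0.24. Nfkbiz and Nfkbia, which encode members of the inhibitor of NF-kB family, had -1.56 ± 0.26 and -1.33 ± 0.25. Tnip3, another inhibitor of the pathway, lay the other way at 1.01 ± 0.25. The list's call was lost among genes of an average log2 CPM of at least 6 (camera adjusted p = 0.0622) and in fry (adjusted p = 0.127). Higher mitochondrial rRNA shares and fewer detected genes went with the LFD libraries here too.

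Other immune lists did not pass. Interferon-stimulated genes had 42 members tested, 18 higher and 24 lower (camera adjusted p = 0.754), with 0 passing adjusted over the list alone and over all genes. Their median of -0.13 was 0.41 below that of all genes, and 0.39 below it with library totals alone, where their own median was 0.62. At an unadjusted edgeR p under 0.05, 3 members were higher and 0 lower. These were Irgm2, Oasl2 and Cmpk2, at 2.51, 1.67 and 1.33 CPM in HFD. Pml, which DESeq2 called lower (adjusted p = 0.0351), had 17.2 ± 0.23 against 42.7 ± 13 CPM. Dendritic cell maturation genes had 26 of 35 higher and 9 lower, with a median of 0.32 against a camera direction of down (adjusted p = 0.824), and 0 passed adjusted over the list alone or over all genes. The costimulatory receptor gene Cd40 (chromosome 2, 165055627 to 165072948) had 17.8 ± 2.99 against 64.1 ± 17.1 CPM and a log2 fold change of -1.85 ± 0.47 (edgeR adjusted p = 0.0864, DESeq2 adjusted p = 0.000102). The adaptor gene Traf1 had -0.67 ± 0.19, while Samsn1 lay the other way at 2.151 ± 0.735. At an unadjusted edgeR p under 0.05, 2 members of this list were higher and 3 lower. Chemokines had 5 of 13 higher and 8 lower, but 10 higher and 3 lower with library totals alone (camera adjusted p = 0.958), and 0 passed adjusted over the list alone or over all genes. Ccl22 and Ccl6 were at 114 ± 23.2 against 63.2 ± 29.3 CPM and 77.04 ± 32 against 15.5 ± 14.7 CPM. The list of pattern recognition receptors and adaptors had 16 of 21 higher and 5 lower (camera adjusted p = 0.589), with 0 passing adjusted over the list alone or over all genes. Irak2 had -1.08 ± 0.32, and Tlr4 had no count in LFD.

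Dissociation and immediate-early genes, which respond within minutes to stimulation, tissue digestion and heat, fell in HFD as a list (camera adjusted p = 3.72e-15, and adjusted p = 0.567 with an estimated correlation). Of 29 members tested, 4 were higher and 25 lower, at a median of -0.84, which is 1.12 below the median of all genes, or 1.13 below it with library totals alone, where the list's own median was -0.12. Adjusted over the list alone 16 passed, 1 of them higher, and 0 passed over all genes. Jun, an AP-1 subunit (chromosome 4, 95049034 to 95052222), had 139 ± 22.4 CPM in HFD and 524 ± 136 CPM in LFD, a log2 fold change of -1.91 ± 0.28. Ier5 (chromosome 1, 155096361 to 155099636) had 463 ± 45.7 against 1175 ± 170 CPM and -1.35 ± 0.19. The heat-shock members, with Hspa1a and Hspa1b among them, had 7 of 8 lower at a median of -1.28, and the immediate-early members 18 of 21 lower at a median of -0.84. The exception that passed adjusted over the list alone was the antiproliferative gene Btg2, at 635 ± 97.5 against 278 ± 38.3 CPM. The mitochondrial rRNA share, higher in the LFD libraries, moved the same way.

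Unfolded protein response genes had 19 of 24 higher and 5 lower, at a median of 0.57 (camera adjusted p = 0.471), and 3 passed adjusted over the list alone, 2 of them higher, against 0 over all genes. The list passed among genes of an average log2 CPM of at least 6 (camera adjusted p = 0.0338). The disulfide isomerase genes Pdia6 and Pdia4 had log2 fold changes of 1.68 ± 0.31 and 1.35 ± 0.27. The stress transcription factor gene Atf3, also an immediate-early gene, had -1.45 ± 0.23. Apoptosis and DNA damage genes had 14 of 22 higher and 8 lower (camera adjusted p = 0.926), with 0 passing adjusted over the list alone or over all genes. The death regulator gene Bcl2l11 had 224 ± 16.6 against 140 ± 15 CPM.

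Lists of metabolism did not pass camera. Nuclear oxidative phosphorylation genes had 37 of 41 higher and 4 lower, at a median of 0.94 (camera adjusted p = 0.0678), with 0 passing adjusted over the list alone or over all genes. Leaving out LFD 1, LFD 2 or LFD 3 left the camera adjusted p at 0.142, 0.255 and 0.188. The list passed without HFD 1 and without both LFD 1 and LFD 2, but not without HFD 3. Each of these fits left 1 library in a group. Uqcrfs1, the Rieske protein of complex III, had 39.6 ± 2.35 against 2.54 ± 2.08 CPM, and Atp5c1 had 76.9 ± 9.68 against 19.0 ± 11.3 CPM. Lipid uptake and storage genes had 18 of 27 higher and 9 lower (camera adjusted p = 0.926), and 1, the lectin gene Lgals3, passed adjusted over the list alone, with 0 over all genes. Lgals3 (chromosome 14, 47367751 to 47386160) had 203.5 ± 27.4 against 77.3 ± 12.6 CPM, the fatty acid translocase gene Cd36 135 ± 37.3 against 47.1 ± 16.4 CPM, and the lysosomal acid lipase gene Lipa 51.9 ± 9.8 against 8.3 ± 3.59 CPM. DESeq2 called these 3 higher, and called Fabp4 lower at 7.68 ± 1.45 against 38.6 ± 5.56 CPM. Fatty acid oxidation genes had 19 of 24 higher and 5 lower (camera adjusted p = 0.465), cholesterol and fatty acid synthesis genes 17 of 31 higher and 14 lower (0.754), and glycolysis and hypoxia genes 13 of 28 higher and 15 lower, but 26 higher and 2 lower with library totals alone (0.762), with 0 passing in these 3 lists adjusted over the list alone or over all genes. Slc25a20, the mitochondrial acylcarnitine carrier, had 208 ± 5.24 against 111 ± 25.3 CPM. The angiogenic factor gene Vegfa had 9.53 ± 3.75 against 55.9 ± 43.3 CPM. Cell cycle genes had 35 of 41 higher and 6 lower, at a median of 0.71 (camera adjusted p = 0.237), with 0 passing adjusted over the list alone or over all genes. Gins2 had 6 ± 1.93 CPM in HFD and no count in LFD.

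**Figure D3:**
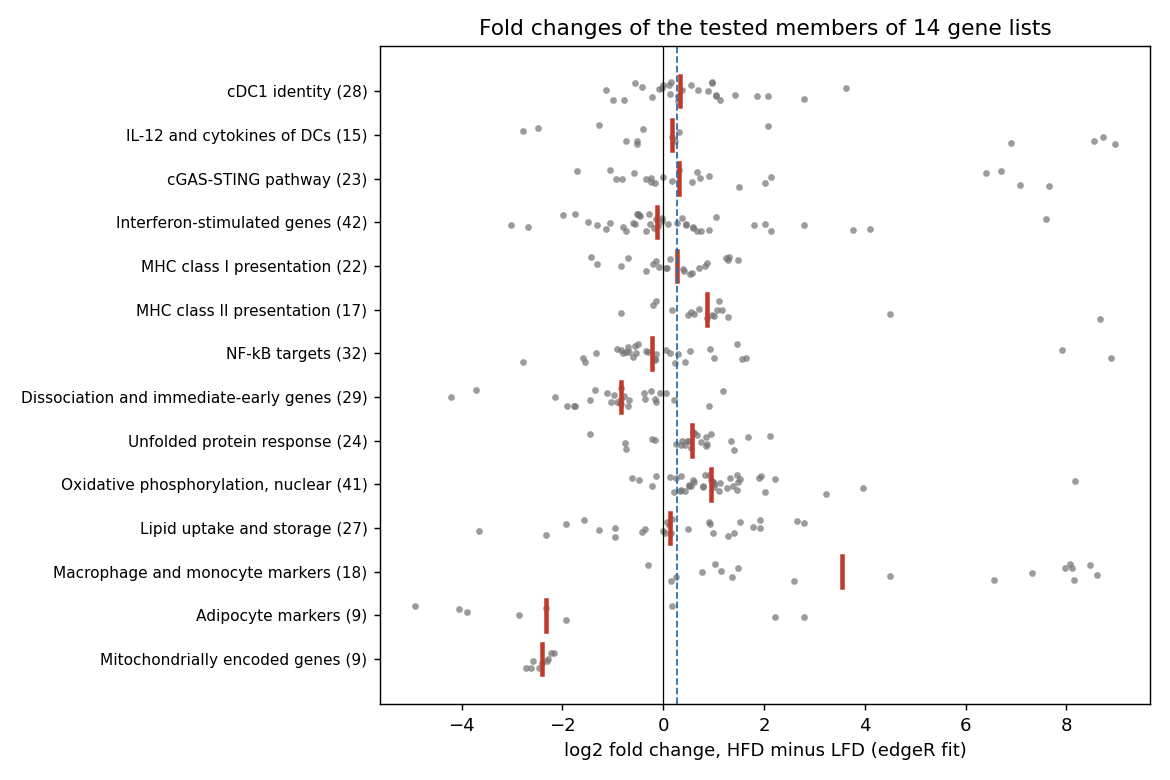
Grey points are the edgeR log2 fold changes (HFD minus LFD) of the tested members of 14 gene lists, with the number tested in brackets, red bars mark each list's median, and the dashed line marks the median of all tested genes at 0.28. Mitochondrially encoded genes lie at a median of -2.40 and macrophage and monocyte markers at 3.54, or 2.94 with members lacking LFD counts at their lower bound. With library totals alone, where the median of all genes is 1.01, the medians of NF-kB targets and interferon-stimulated genes are 0.39 and 0.62, still below it.

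Markers of other cells of the tissue, among them cells that the sort excluded, were measured in the same libraries. Macrophage and monocyte markers rose in HFD as a list (camera adjusted p = 0.000306, and adjusted p = 0.741 with an estimated correlation), although the sort excluded cells carrying CD88 or CD11b. Of 18 members tested, 17 were higher and 1 lower, at a median of 3.54, or 2.94 with the 7 members lacking LFD counts set at their lower bound. Adjusted over the list alone 12 passed, all of them higher, and 0 passed over all genes. Timd4 and Lyz2 were the most abundant, at 189 ± 2.29 against 232 ± 33.4 CPM and 247 ± 79 against 121 ± 26 CPM, and Timd4 was the member that lay lower, except with library totals alone (0.46, where the median of all genes was 1.01). The complement gene C1qa had 14 counts in HFD 1, 129 in HFD 3 and 0 in the LFD libraries. Itgam, which encodes CD11b (chromosome 7, 128062640 to 128118491), had 6.26 ± 0.3 against 5.31 ± 9.21 CPM, with 51 counts in LFD 1 and 0 in LFD 2 and LFD 3, and its log2 fold change of 0.25 ± 2.74 became -0.35 without LFD 2 and -0.41 without LFD 3. Without LFD 1 no LFD count was left, and against 3 counts over LFD 2 and LFD 3 Itgam was 4.52 higher in HFD. That floor covers counting error only. In LFD 1 Itgam was at 15.9 CPM, above the 6.05 and 6.48 CPM of HFD 1 and HFD 3. The zeros in LFD 2 and LFD 3 thus do not bound its level. C5ar1, which encodes CD88, had 16 counts in HFD 1, 59 in HFD 3 and 0 in the LFD libraries. Against a floor of 3 counts over the LFD group, for counting error only, its log2 fold change was 3.28. Without LFD 1 and LFD 2 the list's adjusted p was 0.0518. The LFD libraries also had higher mitochondrial rRNA shares and fewer detected genes.

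Type 2 dendritic cell markers had 9 of 13 higher and 4 lower, at a median of 1.09 (camera adjusted p = 0.0648), and 2 passed adjusted over the list alone against 0 over all genes. Leaving out LFD 1, LFD 2 or LFD 3 left the camera adjusted p at 0.0513, 0.07 and 0.0667. These markers passed without HFD 1 and without both LFD 1 and LFD 2, but not without HFD 3. Each of these fits left 1 library in a group. Their most abundant member, the monocyte chemokine receptor gene Ccr2, had 220 ± 27.1 against 78.6 ± 23 CPM (DESeq2 adjusted p = 0.00295), followed by Clec12a at 46.6 ± 0.018 against 27.9 ± 16.4 CPM. Plasmacytoid dendritic cell markers had 3 of 7 higher and 4 lower, but 4 higher and 3 lower with library totals alone (camera adjusted p = 0.754), with Tcf4 at 30.9 ± 4.79 against 41.9 ± 17.1 CPM and Runx2 at 6.28 ± 2.31 against 24.4 ± 19.8 CPM. The sort excluded cells carrying CD3, TCRβ, NK1.1, CD19 or Ly6G. T and NK cell markers had 3 of 5 higher and 2 lower (camera adjusted p = 0.0838). The camera adjusted p was 0.0187 without LFD 3 but 0.354 without LFD 2. The 3 higher members passed adjusted over the list alone, led by the NKG2D gene Klrk1 at 106 ± 8.34 against 25.1 ± 15.7 CPM. Only 2 B cell markers, Ighm and Cd79b, and 1 neutrophil or mast cell marker, Kit, were tested, too few for camera. Kit had 178 ± 4.41 against 72.4 ± 9.23 CPM (DESeq2 adjusted p = 8.99e-05) and passed adjusted over its list alone, and Ighm had 45.6 ± 10.8 against 41.7 ± 22.9 CPM. No red blood cell gene was tested, and Hbb-bs had 43 counts in LFD 2 and 0 in the other libraries.

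Adipocytes had been removed by centrifugation, and the sort kept CD45-positive cells. Adipocyte markers had 3 of 9 higher and 6 lower, at a median of -2.33 (camera adjusted p = 0.0678). The list passed without LFD 3 (camera adjusted p = 0.00618) but not without LFD 1 (0.662) or LFD 2 (0.597). It also passed without HFD 3 but not without HFD 1, fits that left 1 HFD library. The list's summed level was 165.7 and 189.1 CPM in LFD 1 and LFD 2. In LFD 3 it was 70.72 CPM, close to 69.57 and 65.17 CPM in HFD 1 and HFD 3. Fabp4 (chromosome 3, 10204088 to 10208576) had a log2 fold change of -2.33 ± 0.64 (edgeR adjusted p = 0.105, DESeq2 adjusted p = 9.83e-07), and Lipe had 48.7 ± 5.26 against 43.3 ± 16.1 CPM. Fibroblast and preadipocyte markers had 2 of 13 higher and 11 lower, at a median of -1.19 (camera adjusted p = 0.471), with Dpp4 at 301 ± 25.6 against 204 ± 45.4 CPM and Gsn at 171.5 ± 27.8 against 209.8 ± 87.8 CPM. Endothelial and mesothelial markers had 3 of 7 higher and 4 lower, but 4 higher and 3 lower with library totals alone (camera adjusted p = 0.754), with Cdh5 at 6.12 ± 4.21 against 11.2 ± 9.47 CPM. Of these lists, 2 endothelial and mesothelial members passed adjusted over the list alone, 0 plasmacytoid, adipocyte or fibroblast members did, and 0 members of any passed over all genes.

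Mitochondrially encoded genes fell in HFD as a list (camera adjusted p = 2.08e-09, and adjusted p = 0.741 with an estimated correlation). All 9 tested members were lower, at a median of -2.40, and all 9 passed adjusted over the list alone with 0 over all genes. The large and small mitochondrial rRNA genes mt-Rnr2 and mt-Rnr1 had log2 fold changes of -2.72 ± 0.61 and -2.47 ± 0.63. Fry did not call the list (adjusted p = 0.148). Cytosolic ribosomal protein genes had 31 of 46 higher and 15 lower, at a median of 0.32 (camera adjusted p = 0.824), with 0 passing adjusted over the list alone or over all genes. Rpl4 and Rpl8 were at 626 ± 74.2 against 755 ± 175 CPM and 482 ± 113 against 396.5 ± 138 CPM. Among the sex-linked genes, Xist and Tsix had 0 counts in all 5 libraries, and Ddx3y, Uty, Eif2s3y and Kdm5d had counts in all 5. Ddx3y ranged from 85.7 to 102 CPM over the libraries.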

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

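The settings that left out rRNA-like genes, removed length and GC trends, kept genes of high counts, or left out LFD 1 and LFD 2 were chosen after the data were seen. The count of 0 edgeR calls held with DESeq2 size factors, library totals alone, upper-quartile factors, a CPM filter, robust dispersions off, a threshold of 0.01, thinning, length and GC offsets, without mitochondrial and ribosomal protein genes, without rRNA-like genes and without any one LFD library. It became 205 (68 higher and 137 lower) with no count filter, 1 (Hspa1a, lower) with at least 10 counts in 2 libraries and an average log2 CPM of at least 3, and 974 (760 and 214) at a threshold of 0.1. It became 897 (284 and 613) in DESeq2, 146 (117 and 29) in limma-voom and 1678 (1446 and 232) in limma-voom with sample quality weights, so these tools differ in which direction holds most calls. Among genes of an average log2 CPM of at least 6 it was 262 (108 and 154) of 2109, where fewer genes are tested. It was 7492 (5158 and 2334) without LFD 1 and LFD 2, where the spread comes from the HFD pair. Leaving out one library gave 0 to 68 calls, 0 to 18 higher and 0 to 50 lower, and only leaving out an HFD library, whose remaining partner is assumed to vary like the LFD libraries, gave any. Apart from these constructions, the cause of each change was not tested.

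The replicate numbers 1 and 3 are shared by the diets, but no label says that they mark a shared day, so they are not taken to pair the samples. Deviations of same-numbered libraries from their group means correlated at -0.046 and -0.013. With 2 HFD libraries the HFD deviations mirror each other, so these are not separate checks and cannot decide whether samples were paired. With a replicate block, edgeR called 373 genes (155 higher and 218 lower), and the same 5 lists passed. LFD 2 has no partner in that fit, which leaves little from which to estimate the spread.

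The 5 lists that passed camera all missed the threshold with an estimated correlation (0 lists), at adjusted p of 0.567 for NF-kB targets, 0.567 for dissociation and immediate-early genes, and 0.741 for MHC class II, macrophage and mitochondrially encoded genes. Fry called 9 lists, without NF-kB targets (0.127), macrophage markers (0.0532) and mitochondrially encoded genes (0.148). MHC class II presentation missed it with length and GC offsets (0.0668) and without LFD 1 and LFD 2 (0.0802), and ranged from 0.00377 to 0.142 over the fits without one library. With the offsets its median was 0.65, or 0.54 above that of all genes against 0.58 before. The interquartile range of its members went from 0.61 to 0.87, so the shift was similar and the spread wider. NF-kB targets missed it at an average log2 CPM of at least 6 (0.0622) and macrophage markers without LFD 1 and LFD 2 (0.0518). Macrophage markers had too few genes to be tested at that CPM. Without one library, 4 to 7 lists passed. The cause of these changes, the wider spread for MHC class II among them, was not tested.

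Of 2616 refitted fold changes of the 115 named genes tested, 2181 kept direction and side of the threshold, 396 passed where the main test did not, 0 did the opposite and 39 changed sign, in 20 genes that the main test did not call. With library totals alone, which moved the median of all genes to 1.01, the log2 fold changes became 0.031 for Traf1, 0.46 for Timd4, 0.41 for Tcf4, 0.56 for Gsn, 0.49 for Rpl4, 0.66 for Ddx3y and 0.073 for Kdm5d. Clec9a became -0.021 with DESeq2 size factors and in DESeq2, and Cdh5 became 0.52 in limma-voom and 0.31 with sample quality weights. Gsn became 0.058 with the replicate block. With length and GC offsets, Il12b became -0.38, Clec9a -0.45, Mcl1 -0.009, Clec12a -0.033, Ighm -0.12 and Eif2s3y -0.73. Ddx3y became 0.086 at an average log2 CPM of at least 6. Without LFD 1 and LFD 2, Il12b became -0.40, Clec9a -0.36, Batf3 0.22, Irf8 -0.048, Tcf4 0.45, Cd79b 1.47 (on 1 LFD count) and Gsn 0.64. Over the fits without one library, the log2 fold change ranged from -0.13 to 0.37 for Clec9a, -0.37 to 0.61 for Il12b, -0.46 to 0.93 for Mb21d1, -0.24 to 0.63 for Ighm, -0.13 to 0.024 for Ddx3y, -0.14 to 0.42 for Lipe and -0.36 to 0.99 for Eif2s3y. Tmem173, which kept its sign, ranged from 0.872 to 1.988. Itgam became -0.35 without LFD 2 and -0.41 without LFD 3. Without LFD 1 no LFD count was left, and against 3 counts over LFD 2 and LFD 3 it was 4.52 higher in HFD. That floor covers counting error only, and the fitted 9.13 depends on the prior count and is no measure of the difference. Of 1456 tested genes under a log2 CPM of 1, 98.9% had no count in at least 1 LFD library, and of 1019 genes over 7, 0% did.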

Other observations

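The gene families below were chosen after the fold changes had been seen, as were the tests of sequencing depth, of RNA input, of handling and of other splits of the libraries. Lysosomal genes lay higher in HFD, with 33 of 41 tested members higher and 8 lower at a median log2 fold change of 0.87, and DESeq2 called 10 of them, all higher. Macrophage markers rose in the same comparison (17 of 18 higher, at a median of 2.94 with members lacking LFD counts at their lower bound, and an adjusted p of 0.741 with an estimated correlation), and the LFD libraries had higher mitochondrial rRNA shares and fewer detected genes. Psap, the precursor of the saposins that activate sphingolipid breakdown, had 3248 ± 319 CPM in HFD and 1528 ± 236 CPM in LFD (SD, n = 2 and 3), a log2 fold change of 1.09 ± 0.17. Ctss, Naaa and Ppt1 belong to this family and to the fixed lists. Proteasome subunits had 31 of 37 higher at a median of 0.86, with DESeq2 calling 3, all higher. Psmd14, the deubiquitinase of the proteasome lid, was at 35.4 ± 0.87 against 1.75 ± 1.6 CPM. Vacuolar ATPase subunits had 13 of 17 higher at a median of 0.59, and DESeq2 called 1. Chromatin regulators had 35 of 54 lower at a median of -0.30, or 0.58 below the median of all genes, and 0.55 below it with library totals alone, where their own median was 0.46. DESeq2 called 15, all lower. Among these were the corepressor gene Ncor2, at 164 ± 1.41 against 470 ± 51.1 CPM, and Smarca4, at 257 ± 18.2 against 584 ± 30.3 CPM.

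Against 10000 random lists matched on mean expression, transcript length and GC content, the medians of the fixed lists that passed camera lay at percentile 99.88 for MHC class II presentation, 100 for macrophage markers, 0 for immediate-early genes, 0 for mitochondrially encoded genes and 8.39 for NF-kB targets, the last of these inside the range that held 95% of matched lists. Outside that range without passing camera lay nuclear oxidative phosphorylation (99.98), unfolded protein response (99.71) and cell cycle genes (98.92) above, and interferon-stimulated genes (0.2), fibroblast markers (0.13) and adipocyte markers (0) below. Of the families, the chromatin regulator median lay at percentile 21.84 and the vacuolar ATPase median at 79.27, inside the range. The lysosomal median lay at percentile 100 and the proteasome median at 99.8, but these families were picked because their members lay higher, so the percentiles restate that choice. Random lists were drawn gene by gene, without the correlation between members of a list, so all these percentiles can lie too near 0 or 100.

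The first pattern is that more genes were listed at 0 in the LFD libraries. Depth alone is argued against, since at one thinned total the lower HFD library still had 1.38 times as many genes as the highest LFD library. Of 5002 genes with an HFD mean of 1 to 10 CPM, 1288 were at 0 in every LFD library, 1555 in 2 of them and 1361 in 1, while of 2457 genes with one of 50 to 500 CPM 0 were at 0 in every LFD library. The log2 ratio of summed LFD CPM, zeros included, to summed HFD mean CPM was 0.13, 0.25 and 0.12 lower in the first set of genes than in the second in LFD 1, LFD 2 and LFD 3 (lowest difference -0.25), a difference in which a library's scaling cancels, so the summed level of the first set fell little against the second. This is consistent with fewer RNA molecules reaching the LFD libraries, without showing it, and it leaves open whether the LFD sorts held fewer cells or more degraded RNA. A change of the cells' total RNA with diet was not tested.

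The second pattern is the lower level of immediate-early and heat-shock genes in HFD. With trends on transcript length and GC removed, the list's median went from -0.84 to -0.59. Relative to the median of all genes it went from -1.12 to -0.71. Part of the shift thus went with these trends, which are argued against only as its whole cause. The camera adjusted p of 6.71e-16 there rests on the preset correlation, while the members had an estimated correlation of 0.23. The expression level of the members is also argued against, since the median lay at percentile 0 of matched lists. Those lists were drawn gene by gene. Handling during digestion and sorting that differed between the groups cannot be told apart from diet, because both would lower both classes of member, and the class that moved less had a median of -0.84. The labels give no time or day of the sorts. An effect of diet on the activation of cDC1s in the tissue stays open and was not tested.

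The third pattern is the higher level of macrophage and monocyte markers in HFD. The list's median lay at percentile 100 of lists matched on mean expression, so its rise exceeded that of other genes of like mean level. Those lists were drawn gene by gene, while the members had an estimated correlation of 0.48. The match also used the mean over all libraries, which loss from LFD itself lowers. The percentile thus cannot decide whether loss of low transcripts from the LFD libraries is the whole cause. Macrophages among the sorted HFD cells, despite the CD88 and CD11b gates, cannot be told apart from higher expression in cDC1s. Of 6 macrophage transcripts, 5 (Lyz2, Cd68, C1qa, C1qb and C1qc) were higher in both HFD libraries than in every LFD library. Apoe was not, at 35.4 ± 31.9 against 32.0 ± 33.1 CPM. C1qa, C1qb and C1qc were at only 3.7, 3.6 and 4.6 CPM in HFD, with no LFD count. Of 5002 genes with an HFD mean of 1 to 10 CPM, 1288 were at 0 in every LFD library. Loss from the LFD libraries could thus separate the C1q genes. C1qc had 22 counts in HFD 1, 154 in HFD 3 and 0 in LFD, so its level differed between the HFD libraries themselves. Of the list's 27 genes, 11 had counts in at least 1 LFD library, and Itgam, Ccr2, Csf1r, Ly6c2, Cd14, Apoe and Trem2 are also in other lists.

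The number of genes at an unadjusted p under 0.05 was 2024 for the real grouping. Of the 10 splits of the 5 libraries into 2 and 3, 1 gave as many, the real one, and the highest of the others gave 1318, for LFD 2 and LFD 3 against the rest. With 10 splits no share under 0.05 can be reached.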
